A study of Mus musculus with 12 samples.

How the data were processed

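The study measured chromatin accessibility by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in cells of mouse embryos at embryonic day 7.5. Per the labels, the embryos were homozygous for a FoxA2 allele joined to the red fluorescent protein tagRFP. The allele was either otherwise wild type (WT) or lacked 10 amino acids of an alpha helix of FoxA2 (dHx). Per the labels' protocols, the extraembryonic part was removed before dissociation and embryos of both sexes were mixed. Cells were sorted on tagRFP into High (above the signal of heterozygous cells), Middle (up to that signal) and Negative. The 12 samples form 6 groups of 2, 1 for each genotype and RFP level, taken from the titles and the genotype and RFP labels.

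The deposited files are 6 peak lists, 1 per group, on the mouse build mm10. Per the submitters' processing notes, STAR 2.5.2a and MACS2 were used. Their roles and settings are not given in the sources used here. The peak names in the deposited files hold the words Pooled, Aligned, Filtered and unique, so each list was read as 1 list from the pooled reads of the 2 samples of a group. No value per replicate was used here, and no replicate could be left out.

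The deposited score of each peak was read as the −log10 of a p-value or q-value from the authors' peak caller. This was inferred from the values, because the column has no name. The scores of each list take few distinct values whose steps follow the upper tail of a Poisson distribution with 1 fixed mean. Which of p or q was given is not stated. The authors' scores grow with sequencing depth and were used only to rank or filter peaks within a list. Peak numbers in the names run higher than the number of peaks, and between 9.467% (WT Middle) and 13.37% (dHx High) of the numbers were skipped. The filter behind the skipped numbers is not given in the sources used here.

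A peak with several summits takes several lines with the same start and end, and these were merged into 1 peak. Chromosomes 1 to 19, X and Y were kept, and no line lay elsewhere. For each list, the mean of the Poisson distribution was fitted to the steps between its 40 lowest distinct scores, with the pileup of the lowest score as the other unknown. This fitted background, in mean pileup per base, stands for relative depth only if the authors used the same extension length and genome size for all lists. Its range is the value found when the lowest pileup is 1 step lower or higher. The total number of reads per sample is not given in the sources used here.

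Peak lists were compared by overlap of at least 1 bp. A peak with no overlapping peak in the compared list was called only in its own list. Shares carry Clopper-Pearson 95% intervals. With 1 list per group there was no test between groups and no p-value was computed, since peaks and genes are not replicates.

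Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes. The table gives no strand, so the start of transcription could not be placed. Distance to the gene body (0 inside it) therefore replaced the planned distance to the transcription start, and "within 1 kb of either gene end" replaced the planned promoter class. Each peak was assigned to the nearest protein-coding gene within 100 kb. The genome sequence was not used here, so the planned forkhead motif counts and their alternatives were not run.

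Before the data were examined, 9 gene lists were fixed with 246 entries and 218 distinct genes: definitive endoderm, node and notochord, visceral endoderm, primitive streak and nascent mesoderm, lateral and cardiac mesoderm, blood and endothelium, epiblast and neuroectoderm, extraembryonic ectoderm and trophoblast, and ubiquitous promoters. They are lists of loci and no peak list was called a cell type. By symbol, 216 genes were found. Cerl2 is a synonym of Dand5, which was already listed, and Cripto was not matched, but Tdgf1 was listed. In more than 1 list stood 26 genes. For each list, the share of its peaks found only in 1 of the compared groups was set against 10000 random gene sets of the same size, matched in 5 classes of the number of assigned peaks. The percentile among these sets describes the deposited lists and is not a p-value. The sets were not matched on peak strength, and fewer sets were drawn for the alternatives.

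The rule for named genes was also fixed before the data were examined. It took Foxa2 always. From each list and each contrast it took up to 4 members with the most peaks only in the first group and up to 2 with the most only in the other. Genome-wide it took the 10 genes with the largest and the 10 with the smallest net number. At most 30 were to be printed per contrast, the endoderm, node and visceral lists first. Which of the remaining genes were printed was chosen after their values were seen. Single peaks were the highest-scoring peak only in the first group of Foxa2 and of the named endoderm and node genes.

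For the loss of WT High peaks by their presence in WT Negative, the peaks with a WT Negative peak were weighted to the composition, in 10 classes of score and the gene-end class, of those without one. The same value was computed in 20 simulated draws in which every list held the same accessibility and differed only in fitted background and lowest pileup. Bins of 1 Mb in which the peaks of any list covered at least 100 kb were called dense, after they were seen in the data.

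Alternatives fixed beforehand were 2 overlap rules (at least 50% of the shorter peak covered, or peaks within 500 bp counted as shared), the strongest peaks of each list up to the length of the shortest (37129), the strongest 20000 peaks, the strongest 20000 against the whole other list, autosomes only, a window of 2.5 kb at gene ends, assignment within 50 kb and assignment to every gene within 100 kb. Assignment to the nearest gene end and removal of the dense bins were added after the data were seen.

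The overlap, the background fit, the gene set percentile and the matched difference were tested on simulated data, and the other steps were not. The overlap of 20000 simulated intervals had 0 wrong calls, and the fitted background was recovered with a largest error of 1.79e-05 percent. Those scores were drawn from the same Poisson form that was fitted, so this error says nothing of how well the form suits the deposited scores. Of 200 simulated unchanged gene sets of 30 members among 8000 genes, 93% lay inside the central 95%. Of sets with 60% loss against 40% elsewhere, 97.5% lay above the 97.5th percentile. Simulated peaks were lost independently, whereas some deposited genes had many peaks missing together, so this rate need not hold for the deposited lists. At Middle RFP the central 95% of the sets matched to the endoderm list reached 64.0% WT-only, so 60% would not stand out there. In 200 simulations of 40000 peaks, a planted difference of 0 points gave a mean of 10.1 before and 0.017 after matching, and a planted 15 gave 25 and 15. The 95% interval held the planted value in 96% and 95.5% of them. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.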

Results

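Accessible chromatin was measured by ATAC-seq in cells of mouse embryos at embryonic day 7.5, when the germ layers form. FoxA2 is a forkhead transcription factor of the endoderm, node and notochord, known as a pioneer factor that binds its sites in closed chromatin. The cells carried FoxA2 joined to tagRFP, as wild type (WT) or without 10 residues of an alpha helix (dHx), and were sorted into High, Middle and Negative RFP. The 12 samples formed 6 groups of 2. Each group was given as 1 peak list made from its pooled samples, so no comparison had replicates and no difference between lists was tested.

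The WT High list held 45689 peaks that covered 24.8 Mb, the WT Middle list 48761 peaks (24.9 Mb) and the WT Negative list 39569 peaks (21.6 Mb). The dHx High list held 37129 peaks (21.1 Mb), the dHx Middle list 39121 (21.7 Mb) and the dHx Negative list 50424 (27.8 Mb). The number of reads is not given in the sources used here, and the background fitted to the authors' scores (−log10) stood in for relative depth. It was 0.882 (range 0.840 to 0.924) in WT High and 0.478 (0.454 to 0.502) in dHx High. It was 1.497 in WT Middle, 0.789 in dHx Middle, 1.08 in WT Negative and 1.57 in dHx Negative, in mean pileup per base. At each RFP level, the genotype with the higher background had more peaks. The lowest-scoring peaks stood 6.27-fold over background in dHx High and 3.83-fold in dHx Negative, so the lists differed in how weak a peak they could hold.

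**Figure D1:**
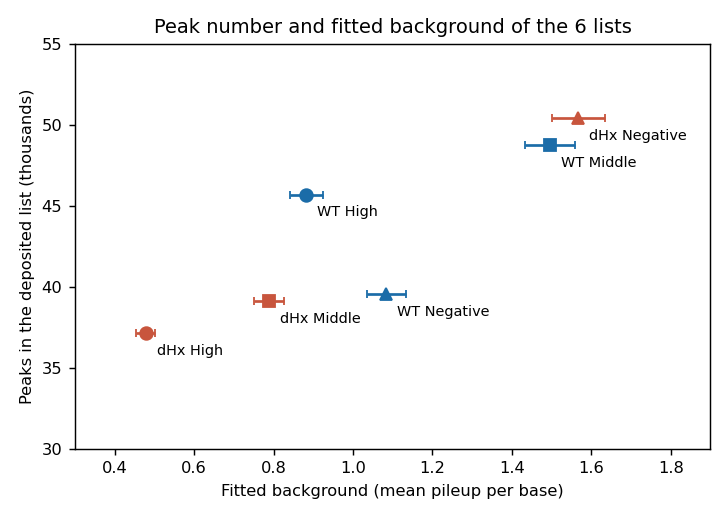
Number of peaks in each deposited list (vertical axis, in units of 1000, starting at 30) against its fitted background (horizontal axis, mean pileup per base). Blue is WT and red dHx, circles are High, squares Middle and triangles Negative RFP, and horizontal bars give the background when the lowest pileup is 1 step lower or higher; dHx High has the lowest background (0.478) and the fewest peaks (37129).

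The Foxa2 gene itself (mm10, chromosome 2, 148042877 to 148046969) had 16 assigned peaks in WT High, 19 in WT Middle, 11 in WT Negative, 16 in dHx High, 20 in dHx Middle and 15 in dHx Negative. A region that overlapped the gene, from 148045181 to 148047200, held a peak in all 6 lists, as did 148052730 to 148054055, outside the gene and 147968035 to 147969177, the farther of the 2 from the gene. The region 147989681 to 147990466 held a peak in the 4 RFP-positive lists and in neither Negative list. The region 148065683 to 148066327 held a peak in WT Middle, dHx High and dHx Middle.

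**Figure D2:**
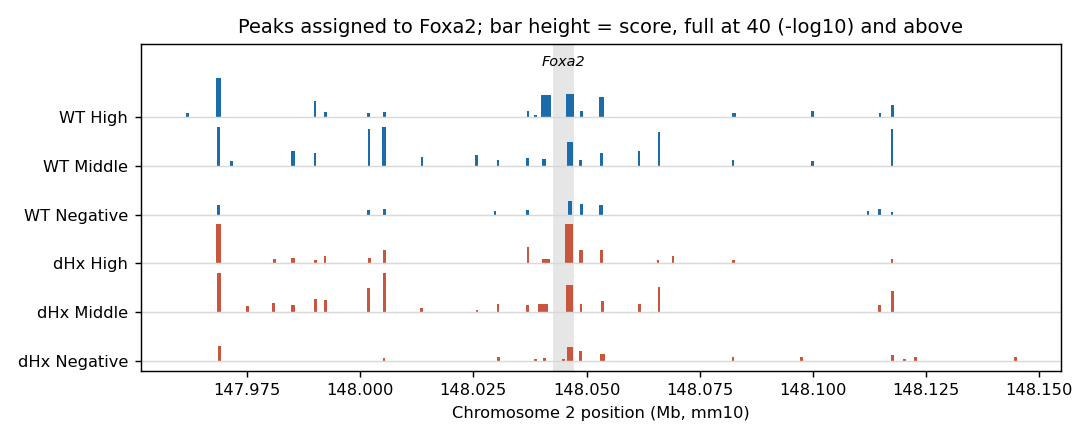
Peaks assigned to Foxa2 in the 6 lists along chromosome 2 (Mb, mm10), blue for WT and red for dHx, with the gene body in grey. Bar height is the authors' score, full at 40 (−log10) and above, and bars are drawn wider than narrow peaks; scores are not comparable between lists, and both Negative lists lack the peak at 147989681 to 147990466.

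The first comparison asked which regions were open in WT cells with the most FoxA2 and not in cells without it. Definitive endoderm had more genes on the High side, with a High-only share near the upper end of the central 95% of random sets. Cdh1, which encodes E-cadherin, had 8 High-only peaks among its 10 in WT High and 1 Negative-only peak among 3 in WT Negative. Shh, the hedgehog ligand of the notochord, had 5 of 6 against 0 of 1, and Noto, a homeobox factor of the node, had 4 of 5 against 0 of 1. Hand1, a factor of lateral and extraembryonic mesoderm, had no WT High peak and 6 peaks in WT Negative, all Negative-only. Foxa2 had 7 High-only peaks of 16 against 2 Negative-only of 11.

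Of the WT High peaks, 22399 (49.0%, 48.6 to 49.5) had no WT Negative peak, and 16236 of the WT Negative peaks (41.0%, 40.5 to 41.5) had no WT High peak. These and all later intervals are Clopper-Pearson 95% intervals and cover counting error only. The standard errors (SE) given later treat peaks as independent and also cover counting error only, not variation between samples. Peaks near definitive endoderm genes were High-only in 89 of 143 cases (62.2%, 53.8 to 70.2), at the 97.0th percentile of matched random gene sets, whose central 95% reached 62.7%. In that list 21 genes had more High-only peaks, 4 had more Negative-only peaks and 4 had equal numbers. Krt18, a keratin, had 6 of 10 against 0 of 4, Cxcr4, a chemokine receptor, 6 of 9 against 3 of 6, and Emb, a membrane glycoprotein, 3 of 10 against 6 of 13. In the node and notochord list, 53 of 93 peaks (57.0%, percentile 79.8) were High-only and 44 of 83 (53.0%, percentile 93.3) Negative-only, with 16 genes on the High side, 10 on the Negative side and 1 equal. Lhx1 had 4 of 6 against 2 of 4 and Gsc 5 of 6 against 6 of 7, while Nog, a BMP antagonist, had 2 of 3 against 7 of 8 and Sox9 2 of 6 against 7 of 11. In the visceral endoderm list, 29 of 55 peaks (52.7%, percentile 68.8) were High-only, with 10 genes on the High side, 5 on the Negative side and 4 equal. Ttr, which encodes transthyretin, had 4 of 4 against no peak, Sox17 5 of 9 against 1 of 4, and Slc2a2, a glucose transporter, 0 of 1 against 2 of 3.

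Lateral and cardiac mesoderm loci stood on the Negative side. Of the peaks near lateral and cardiac mesoderm genes, 57 of 93 in WT Negative (61.3%, 50.6 to 71.2) were Negative-only, at the 99.9th percentile, with 15 genes on the Negative side, 9 on the High side and 4 equal. Prrx1, a mesenchymal homeobox factor, had 6 Negative-only peaks of 7 and none of 1 in High. Of those near extraembryonic ectoderm and trophoblast genes, 38 of 60 (63.3%, percentile 99.5) were Negative-only, led by Eomes with 8 of 12, and 9 genes were on the Negative side, 7 on the High side and 1 equal, while 23 of 47 (48.9%) were High-only. With peaks given to every gene within 100 kb, this list turned to 11 genes on the High side and 6 on the Negative side. Hand1, Bmp4 and Eomes belong to more than 1 list. In the streak list, 30 of 76 WT High peaks (39.5%, percentile 5.205) were High-only and 38 of 83 (45.8%, percentile 62.6) Negative-only, with 8 genes on the High side, 9 on the Negative side and 9 equal, and Cdh2, which encodes N-cadherin, had 3 of 8 against 0 of 5. In the blood and endothelium list, 35 of 63 (55.6%, percentile 88.3) were High-only, with 9 genes on the High side, 10 on the Negative side and 5 equal. Runx1 had 11 of 15 against 1 of 5, and Flt1, a VEGF receptor, 0 of 5 against 5 of 10. In the epiblast and neuroectoderm list, 46 of 111 (41.4%, percentile 5.23) were High-only, with 9 genes on the High side, 15 on the Negative side and 6 equal. Sox11 had 7 of 9 against 0 of 2, and Zic1 0 of 1 against 5 of 6. The ubiquitous list had 19 of 57 (33.3%, percentile 4.705), with 5 genes on the High side, 6 on the Negative side and 13 equal.

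Single High-only peaks lay both in and outside genes (mm10). The highest-scoring 1 of Noto (chromosome 6, 85415452 to 85416292, score 31.0) lay 8.01 kb outside the gene and was present in WT Middle, dHx High and dHx Middle. That of Shh (chromosome 5, 28563115 to 28563858, score 9.29) lay 96.4 kb outside the gene, and that of Cdh1 (chromosome 8, 106610847 to 106611345, score 18.1) lay inside the gene, 7.75 kb from its nearer end. Genome-wide, Magi1, a scaffold protein of cell junctions, had the largest net number with 18 of 21 High-only against 3 of 6. The smallest net number belonged to Zfp993 (17 of 37 against 55 of 72), a gene of a repeated zinc finger family whose peaks are uncertain.

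**Figure D3:**
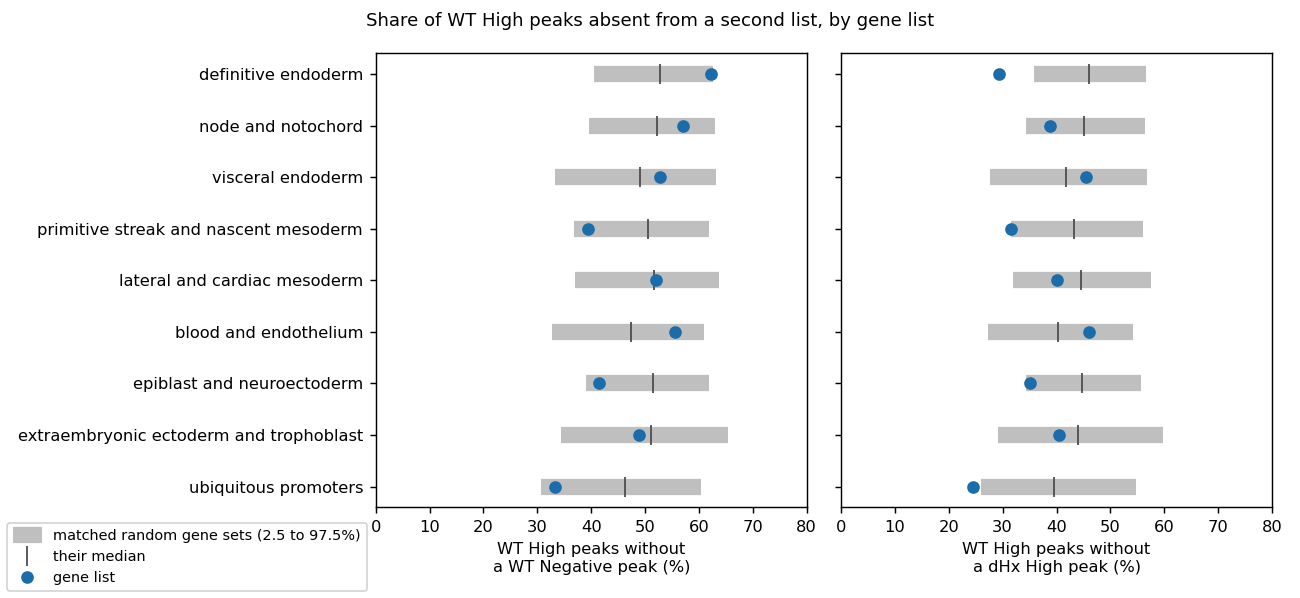
Share (%) of the WT High peaks near the genes of each list that had no WT Negative peak (left panel) or no dHx High peak (right panel). Dots are the gene lists, grey bars the central 95% of 10000 matched random gene sets and ticks their medians; the definitive endoderm dot stands at 62.2% in the left panel and at 29.4%, below its grey bar, in the right panel.

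Among WT peaks, 41.5% of High, 39.0% of Middle and 47.8% of Negative peaks were present at all 3 RFP levels. At no other level were 31.9%, 34.5% and 28.5%. High peaks shared with Middle alone made up 17.1% and those shared with Negative alone 9.52%.

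The same contrast in dHx embryos asked which regions were open in the mutant cells with the most tagged FoxA2. Across all genes, 37.7% of dHx High peaks were High-only and 52.3% of dHx Negative peaks were Negative-only. Definitive endoderm genes stood on the High side. Node genes had nearly as many High-only as Negative-only peaks, but set against random gene sets their High-only share was also high. Cdh1 had 7 High-only peaks of 9 against 1 Negative-only of 3, and Spink1, a secreted protease inhibitor, 5 of 5 against no peak. Shh had 5 of 5 against 2 of 2 and Noto 4 of 5 against 1 of 2. Flt1 had 0 of 3 against 12 of 15, and Tfap2c, a factor of trophoblast and germ cells, 0 of 2 against 8 of 10. Foxa2 had 8 of 16 against 7 of 15.

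Of the dHx High peaks, 14450 (38.9%, 38.4 to 39.4) had no dHx Negative peak, and 27416 of the dHx Negative peaks (54.4%, 53.9 to 54.8) had no dHx High peak. With lists of equal length these shares were 45.4% and 45.1%. In the definitive endoderm list, 78 of 132 peaks (59.1%, 50.2 to 67.6) were High-only, at the 99.9th percentile, with 21 genes on the High side, 4 on the Negative side and 4 equal. Prdm1, a zinc finger repressor, had 6 of 9 against 3 of 6, Otx2 4 of 6 against 4 of 6, and Gata4 2 of 4 against 5 of 7. In the node list, 52 of 92 (56.5%, percentile 99.5) were High-only and 53 of 93 (57.0%, percentile 45.2) Negative-only, with 11 genes on the High side, 10 on the Negative side and 5 equal. Ptch1, the hedgehog receptor, had 5 of 9 against 6 of 10, Sox9 5 of 9 against 8 of 12 and Gsc 3 of 4 against 6 of 7. In the visceral endoderm list, 26 of 49 (53.1%, percentile 95.9) were High-only and 28 of 48 (58.3%, percentile 59.3) Negative-only, with 9 genes on the High side, 7 on the Negative side and 4 equal. Gata6 had 5 of 6 against 2 of 3, Amn 2 of 2 against 1 of 1, Sox17 3 of 6 against 3 of 6, and Cubn, a receptor of absorptive epithelia, 0 of 2 against 6 of 7.

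On the dHx Negative side, 83 of 128 lateral and cardiac mesoderm peaks (64.8%, percentile 81.1) and 55 of 84 blood and endothelium peaks (65.5%, percentile 89.2) were Negative-only. In the lateral list 20 genes were on the Negative side, 5 on the High side and 3 equal, and in the blood list 14, 3 and 6. Tbx3 had 8 Negative-only peaks of 10, Msx1 8 of 13, Runx1 7 of 12 and Pax2, of the epiblast and neuroectoderm list, 9 of 11. That list had 83 of 149 Negative-only (55.7%, percentile 21.4), with 22 genes on the Negative side and 5 on the High side, the streak list 48 of 99 (48.5%, percentile 11.7), with Eomes at 6 of 12, the extraembryonic list 39 of 69 (56.5%, percentile 51.8) and the ubiquitous list 15 of 56 (26.8%, percentile 0.185). The highest-scoring High-only peak of Cdh1 in dHx (mm10, chromosome 8, 106672599 to 106673113, score 38.6) lay 2.61 kb outside the gene and was also present in WT High, WT Middle and dHx Middle. That of Shh (chromosome 5, 28563067 to 28563966, score 26.6) lay 96.4 kb outside the gene and overlapped the High-only peak of WT. Agap1 had the largest net number, with 14 of 21 High-only against 4 of 11. Gm4724, a multi-copy gene with uncertain peaks, had the smallest with 4 of 18 against 89 of 104. All 3 levels shared 47.7% of dHx High, 45.5% of Middle and 35.6% of Negative peaks, and 25.1%, 25.9% and 42.7% were at no other level.

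The main comparison, WT against dHx at High RFP, asked which open regions differed when FoxA2 lacked the helix in cells with the most of it. Near definitive endoderm genes few WT peaks were missing from dHx: 42 of 143 (29.4%, 22.1 to 37.6), at the 0.0400th percentile of matched random gene sets, whose median was 46.0%. Across all genes 40.9% of WT High peaks were WT-only, and near the ubiquitous genes 24.6% were. Foxa2 had 4 WT-only peaks of 16 and 4 dHx-only peaks of 16. Sox17, an HMG-box factor needed for definitive endoderm, had 3 WT-only of 9 against 1 dHx-only of 6. Runx1, a factor of blood formation, had 8 of 15 against 2 of 8, and Six3, a homeobox factor of the anterior neural plate, 5 of 9 against 1 of 6. Evx1, of the primitive streak, had 2 of 2 against 6 of 6, and Isl1, a LIM homeobox factor, 0 of 3 against 5 of 8.

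WT High held 19635 peaks without a dHx High peak (43.0%, 42.5 to 43.4) and dHx High 11356 without a WT High peak (30.6%, 30.1 to 31.1). With lists of equal length the shares were 35.5% and 35.9%, a near symmetry that equal length brings about. For the strongest 20000 peaks of each list looked up in the whole other list they were 18.4% and 12.6%. WT-only peaks were weaker, with a median score of 3.97 against 9.29 for shared WT High peaks. Of the weakest 10% of WT High peaks 77.7% were WT-only, and of the strongest 10% it was 6.26%.

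In the definitive endoderm list, 13 genes had more WT-only peaks, 7 had more dHx-only peaks and 10 had equal numbers, and the dHx-only share was also low (35 of 132, 26.5%, percentile 6.25). Emb had 4 of 10 against 2 of 8, while Gata4, a zinc finger factor, had 3 of 4 and Cxcr4 3 of 9 in both directions. The share of endoderm peaks missing stayed at or below the 0.250th percentile under the alternatives except with peaks given to every gene within 100 kb, where it was at 5.50. In the node and notochord list, 36 of 93 WT peaks (38.7%, percentile 12.2) were WT-only and 37 of 92 dHx peaks (40.2%, percentile 90.9) dHx-only, with 9 genes on either side and 8 equal. Gsc had 5 of 6 against 3 of 4, Lefty1, a Nodal antagonist, 3 of 3 against 2 of 2, Shh 3 of 6 against 2 of 5 and Ptch1 3 of 8 against 4 of 9. In the visceral endoderm list, 25 of 55 (45.5%, percentile 69.7) were WT-only, with 11 genes on the WT side, 6 on the dHx side and 4 equal. Apob had 3 of 4 against 1 of 2, Hnf4a 2 of 2 against 1 of 1, and Lrp2, which encodes megalin, 1 of 2 against 3 of 4.

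In the primitive streak list, 24 of 76 WT peaks (31.6%, percentile 2.46) were WT-only, with 7 genes on either side and 12 equal, and Cdh2 had 4 of 8 against 1 of 5. The lateral and cardiac mesoderm list had 30 of 75 (40%, percentile 24.1), with 9 genes on the WT side, 8 on the dHx side and 6 equal, a dHx-only share of 32 of 77 (41.6%, percentile 94.0), and Msx1 had 3 of 7 against 6 of 10. The blood and endothelium list had 29 of 63 (46.0%, percentile 79.4), with 11 genes on the WT side, 2 on the dHx side and 10 equal. Gata1 had 2 of 2 WT-only peaks and no dHx High peak, and Cd34 0 of 1 against 2 of 3. The epiblast and neuroectoderm list had 39 of 111 (35.1%, percentile 3.51), with 12 genes on the WT side, 9 on the dHx side and 8 equal. Sox2 had no WT High peak and 4 dHx-only peaks, and Sox1 had 3 of 4 against 0 of 1. The extraembryonic list had 19 of 47 (40.4%, percentile 32.4), with 4 genes on the WT side, 6 on the dHx side and 6 equal, a dHx-only share of 23 of 52 (44.2%, percentile 95.7), and Wnt7b had 3 of 4 against 4 of 5. The ubiquitous list had 14 of 57 (24.6%, percentile 1.495), with 5 genes on the WT side, 3 on the dHx side and 17 equal, and Ywhaz 6 of 12 against 0 of 5.

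The highest-scoring WT-only peak of Foxa2 (mm10, chromosome 2, 148099791 to 148100149, score 5.97) lay 53.0 kb outside the gene and was also present in WT Middle. That of Emb (chromosome 13, 117152357 to 117152693, score 23.6) lay 68.0 kb outside the gene and was in no other list. That of Sox17 (chromosome 1, 4533936 to 4534273, score 5.97) lay 36.7 kb outside, and that of Lefty1 (chromosome 1, 180934459 to 180934768, score 7.04) 0.41 kb outside, both in no other list. That of Gata4 (chromosome 14, 63239476 to 63239712, score 3.97) lay inside the gene. Genome-wide, the largest net numbers belonged to Zfp978 (28 of 32 WT-only against 0 of 5) and Zfp993 (28 of 37 against 2 of 10), and 8 of the 10 such genes lay in 1-Mb bins dense in peaks. They are multi-copy genes and uncertain. Outside such bins, Alkbh5, an RNA demethylase, had 23 of 28 against 1 of 6, but at Negative RFP it had 0 of 18 against 16 of 33, so at both levels the list with the higher background had more. On the dHx side, Lifr, the receptor of leukemia inhibitory factor, had 0 of 2 against 9 of 11, and Mtss1 2 of 6 against 10 of 14.

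**Figure D4:**
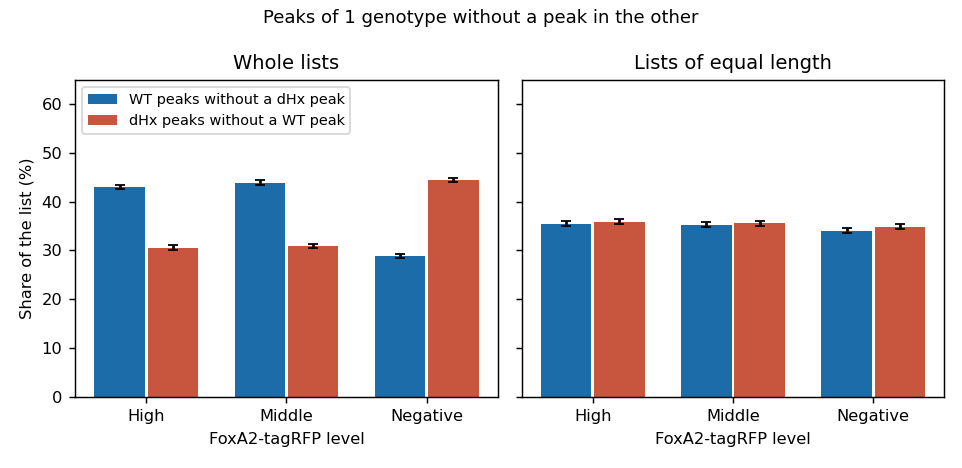
Share of each list (%) without a peak in the other genotype at the same RFP level, for whole lists (left panel) and for the strongest 37129 peaks of each list (right panel). Blue bars are WT peaks without a dHx peak, red bars dHx peaks without a WT peak, and error bars are Clopper-Pearson 95% intervals; at High RFP the shares are 43.0% and 30.6% for whole lists and 35.5% and 35.9% at equal length.

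At Middle RFP, the question was the same in cells with less tagged FoxA2. Across all genes 42.4% of WT peaks were WT-only and 30.1% of dHx peaks dHx-only. Near definitive endoderm genes 39 of 152 WT peaks (25.7%, 18.9 to 33.4) were missing from dHx, at the 0.0200th percentile, while 44 of 152 dHx peaks (28.9%, percentile 25.02) were missing from WT. Gata6, a zinc finger factor of primitive endoderm, had 5 WT-only peaks of 7 against 0 of 2, Emb 7 of 18 against 1 of 11 and Prdm1 6 of 12 against 2 of 8. Gata4 had 0 of 5 against 5 of 10 and Krt18 0 of 5 against 3 of 7. Foxa2 had 3 of 19 against 4 of 20.

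WT Middle held 21417 peaks without a dHx Middle peak (43.9%, 43.5 to 44.4) and dHx Middle 12102 without a WT Middle peak (30.9%, 30.5 to 31.4). At equal length the shares were 35.3% and 35.6%. In the endoderm list 8 genes were on the WT side, 16 on the dHx side and 4 equal, and Otx2 had 3 of 7 against 0 of 4. In the node list, 29 of 90 (32.2%, percentile 5.54) were WT-only, with 8 genes on the WT side, 13 on the dHx side and 6 equal. Bicc1, an RNA-binding protein of the node, had 4 of 8 in both directions, Sox9 4 of 8 against 2 of 6 and Noto 2 of 4 against 1 of 3. In the visceral endoderm list, 28 of 81 (34.6%, percentile 11.8) were WT-only, with 10 genes on the WT side, 8 on the dHx side and 6 equal. Apob had 5 of 8 against 2 of 5, Lrp2 4 of 5 against 2 of 3 and Cubn 3 of 5 against 2 of 4.

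The lateral and cardiac mesoderm list stood out on the dHx side, with 34 of 72 dHx peaks (47.2%, 35.3 to 59.3) absent from WT, at the 98.5th percentile. The WT-only share of that list was also 34 of 72 (percentile 73.6), and 12 genes were on the WT side, 7 on the dHx side and 9 equal. Bmp4 had 4 of 4 in both directions, and Tbx5, a factor of heart and forelimb, 3 of 3 WT-only peaks and no dHx peak. The streak list had 20 of 74 WT-only (27.0%, percentile 1.47) and Pdgfra 5 of 9 against 0 of 4, while Fgf8 had 0 of 1 against 3 of 4. The blood list had 21 of 61 (34.4%, percentile 28.0), with Runx1 at 7 of 12 against 2 of 7 and Tal1 with no WT peak and 3 dHx-only peaks. The epiblast list had 32 of 92 (34.8%, percentile 12.9), and Pax2 had 1 of 2 against 6 of 7. The extraembryonic list had 33 of 58 (56.9%, percentile 84.1) and the ubiquitous list 19 of 65 (29.2%, percentile 6.76). The highest-scoring WT-only peak of Prdm1 (mm10, chromosome 10, 44528358 to 44528698, score 8.45) lay inside the gene 0.03 kb from its end. That of Sox9 (chromosome 11, 112791597 to 112791807, score 11.6) lay 3.94 kb outside, and both were in no other list. Zfp993 had the largest net number (86 of 95 against 0 of 9) and Zfp970 the smallest (2 of 20 against 54 of 68), both multi-copy and uncertain.

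At Negative RFP, the comparison gave the differences between genotypes in cells without detected FoxA2-tagRFP. Across all genes 43.3% of dHx peaks were dHx-only and 27.8% of WT peaks WT-only, and mesoderm, blood and neural genes shared this excess without standing above random gene sets. Runx1 had 1 WT-only peak of 5 against 8 dHx-only of 12, Flt1 1 of 10 against 5 of 15 and Ncam1, a neural adhesion molecule, 1 of 2 against 6 of 7. On the WT side, Emb had 6 of 13 against 2 of 9 and Hand1 5 of 6 against 3 of 4. Foxa2 had 5 of 11 against 9 of 15.

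WT Negative held 11411 peaks without a dHx Negative peak (28.8%, 28.4 to 29.3) and dHx Negative 22423 without a WT Negative peak (44.5%, 44.0 to 44.9). At equal length the shares were 34.1% and 34.9%. In the endoderm list, 33 of 84 (39.3%, percentile 94.8) were WT-only, inside the central 95% of the random sets. In that list 7 genes were on the WT side, 12 on the dHx side and 7 equal, and Otx2 had 3 of 5 against 4 of 6. The node list had 27 of 83 (32.5%, percentile 74.2), and Nog had 4 of 8 against 3 of 7, Sox9 4 of 11 against 5 of 12 and Rfx3, a factor of ciliated cells, 3 of 4 against 0 of 1. The visceral list had 10 of 39 (25.6%, percentile 35.95), and Slc2a2 had 2 of 3 against 0 of 1 and Cubn 0 of 2 against 5 of 7. The lateral list had 29 of 93 (31.2%, percentile 67.0) WT-only, with 4 genes on the WT side, 17 on the dHx side and 7 equal, and 63 of 128 (49.2%, percentile 59.7) dHx-only. The blood list had 14 of 58 (24.1%, percentile 26.7), with 4 genes on the WT side and 13 on the dHx side, and 39 of 84 (46.4%, percentile 57.3) dHx-only. The epiblast list had 33 of 120 (27.5%, percentile 32.4), with 5 genes on the WT side and 17 on the dHx side, and 61 of 149 (40.9%, percentile 9.645) dHx-only. The streak list had 21 of 83 (25.3%, percentile 24.8) WT-only and 36 of 99 (36.4%, percentile 7.555) dHx-only, the extraembryonic list 23 of 60 (38.3%, percentile 88.6) and the ubiquitous list 10 of 53 (18.9%, percentile 9.90). The highest-scoring WT-only peak of Rfx3 (mm10, chromosome 19, 27769710 to 27769982, score 8.13) lay inside the gene, 8.12 kb from its nearer end. That of Emb (chromosome 13, 117218267 to 117218581, score 7.08) lay 2.15 kb outside its gene. Zfp993 again had the largest net number (59 of 72 against 10 of 25) and Zfp970 the smallest (1 of 16 against 81 of 92), both uncertain.

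A further comparison asked whether the WT High peaks that WT Negative lacked were missing from dHx High more often than the rest. They were missing in 62.6% of 22399 cases, against 24.1% of the 23290 with a WT Negative peak. Noto and Shh were among the exceptions, since their highest-scoring High-only peaks were present in dHx High. Matched on score and gene-end class, the difference was 17.4 points (SE 0.544). The mirrored difference, for WT Negative peaks without and with a WT High peak looked up in dHx Negative, was 29.2 points (SE 0.579). The same differences starting from the dHx lists were 22.7 points for dHx High and 24.5 points for dHx Negative. Lists simulated with the same accessibility in all groups gave 29.2 points for WT High, 25.5 for WT Negative, 47.1 for dHx High and 17.5 for dHx Negative. In them 17.1% of WT High peaks lacked a WT Negative peak, against 49.0% observed. Both absences fell on 14018 WT High peaks, against 9626 if they were independent.

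Peaks absent from the other genotype lay away from gene ends, as did peaks absent from another RFP level of the same genotype. Within 1 kb of either end of a protein-coding gene stood 38.1% (37.5 to 38.7) of the WT High peaks shared with dHx High and 8.43% (8.05 to 8.83) of the WT-only peaks. For dHx High these shares were 37.8% and 15.1%. At Middle RFP they were 32.7% and 10.0% for WT and 32.2% and 14.5% for dHx, and at Negative RFP 34.4% and 12.4% for WT and 34.4% and 11.5% for dHx. Between genes lay 50.7% of the WT-only and 41.2% of the dHx-only peaks at High RFP. Within WT, 39.2% of High peaks shared with Negative and 10.9% of High-only peaks stood near a gene end. Within dHx these shares were 42.6% and 12.3%. The split was therefore not particular to genotype. Peaks in only 1 of the compared lists were also the weaker ones, and these shares were not matched on score.

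Peaks were also concentrated in 27 bins of 1 Mb, forming 14 domains, in which the peaks of at least 1 list covered 100 kb or more. These domains hold repeated gene families, such as the Mup genes of major urinary proteins on chromosome 4 (60 to 62 Mb), the Defb genes of defensins on chromosome 8 (19 to 21 Mb) and zinc finger genes on chromosome 2 (175 to 178 Mb) and chromosome 4 (146 to 148 Mb). They held 4.93% of WT High, 10.3% of WT Middle, 6.43% of WT Negative, 2.79% of dHx High, 6.09% of dHx Middle and 9.89% of dHx Negative peaks. The domain on chromosome 2 was covered over 147 kb in WT High and 162 kb in dHx High, 270 kb and 720 kb at Middle, and 225 kb and 1061 kb at Negative RFP. The zinc finger domain at 146 to 148 Mb of chromosome 4 went the other way, with 109 kb in WT High and 23.9 kb in dHx High, 276 kb and 28.9 kb at Middle, and 269 kb and 63.3 kb at Negative RFP. As a share of covered length, 8 of the 14 domains were higher in WT at High and Middle and in dHx at Negative RFP, the order of the fitted backgrounds. The 5 chromosome X domains were among these 8 and were covered mainly in WT Middle. Another 5 domains were higher in the same genotype at all 3 levels. WT Middle alone had 4222 peaks on chromosome X, against 1059 to 2180 in the other lists.

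**Figure D5:**
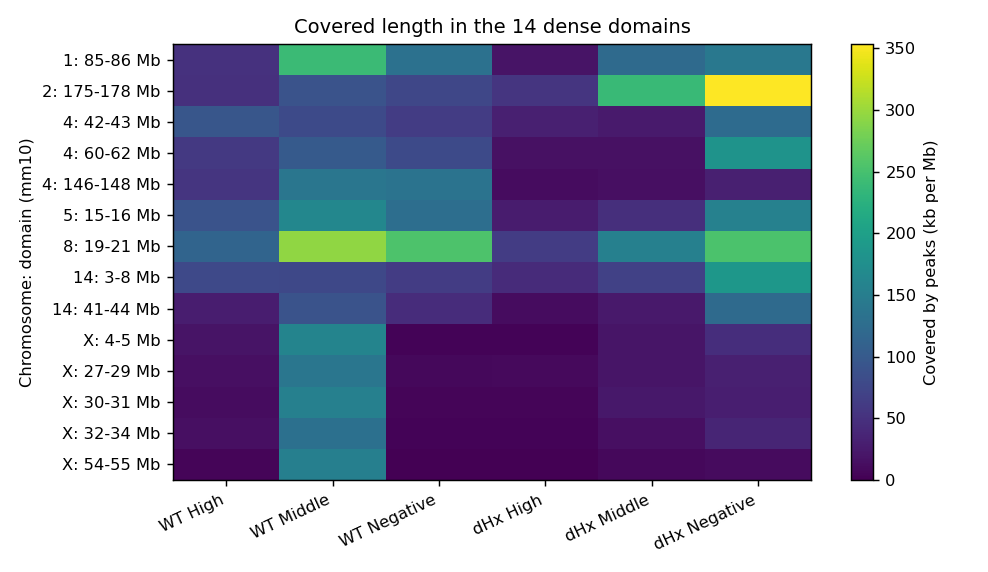
Length covered by peaks (colour, kb per Mb) in each of the 14 dense domains (vertical axis, chromosome and mm10 position) for the 6 lists (horizontal axis). The domain at 175 to 178 Mb of chromosome 2 is brightest in dHx Negative (1061 kb in all), and the 5 chromosome X domains are covered mainly in WT Middle.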

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

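The values below stood out because the difference between genotypes had opposite signs at High and at Negative RFP. The depth and endoderm tests were chosen only after the result was seen, and the test of peaks missing from any other list was chosen before it. These differences were not tested, since each group had 1 list. The dHx list minus the WT list was −8560 peaks at High, −9640 at Middle and 10855 at Negative RFP.

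Of the 9 gene lists, 7 changed sign between High and Negative RFP and are given here for that reason. For definitive endoderm genes, dHx minus WT was −11 peaks at High and 4 at Negative RFP. It was −1 and 10 for node and notochord genes, −6 and 9 for visceral endoderm genes, and −1 and 16 for primitive streak genes. It was −18 and 26 for blood and endothelium genes, −6 and 29 for epiblast and neuroectoderm genes, and −6 and 3 for ubiquitous genes. In the same assignment lateral and cardiac mesoderm genes had 2 and 35 and extraembryonic genes 5 and 9. The signs depended on the setting. Within 50 kb, node genes had 3 and 7 and endoderm genes −6 and 0. With every gene within 100 kb, lateral mesoderm genes had −4 and 52 and extraembryonic genes −2 and 28. At equal length, endoderm genes had 8 and −19, node genes 14 and −3 and epiblast genes 16 and −8, opposite to the values of whole lists.

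The turn may reflect depth or an effect of genotype. The fitted backgrounds ordered the genotypes as the peak numbers did at all 3 levels, with dHx to WT ratios of 0.542, 0.527 and 1.45. At 10-fold over background and more, the dHx to WT ratio of peak numbers was 1.28 (SE 0.0116) at High, 1.27 at Middle and 0.956 at Negative RFP, on the other side of 1 from the 0.813, 0.802 and 1.27 of whole lists. Depth and genotype cannot be told apart, because 10-fold needs a pileup of 9 in WT High and 5 in dHx High. Counting noise may therefore lift more peaks of the shallower list, which was not measured. Reads per sample, drawn to equal numbers, would separate them.

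The greater loss of WT High peaks that WT Negative lacked could come from a FoxA2 effect or from weak peaks that any other list lacks. The mirrored contrast at Negative RFP had the larger difference, and the High difference minus the mirrored difference was −11.8 points (SE 0.795). Simulated lists without a true difference do not help here, since 17.1% of their WT High peaks lacked a WT Negative peak against 49.0% observed. A mirrored difference at least as large was the result set beforehand for peaks that are missing from any other list. The 2 differences were taken in dHx High and dHx Negative, whose fitted backgrounds were 0.478 and 1.57, so depth may enter the −11.8 points. With lists of equal length the differences were 16.4 points at High and 30.1 points for the mirrored contrast. A FoxA2 effect was not excluded.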

How the results depend on the processing

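The tests behind the values compared here were chosen only after the result was seen for depth, copy number and endoderm loss, and before it for the others. Depth may limit every share, because a deeper list can hold weaker peaks, and read numbers per sample were not used here. The fitted background did not order all lists by peak number. WT Negative had a higher background than WT High (1.08 against 0.882) but fewer peaks (39569 against 45689). Pooled lists allow no variance between embryos. No paired analysis was possible because each group was given as 1 list from its pooled samples. For the same reason no replicate was left out. The motif alternatives and those based on transcription starts were not run, because sequence and strand were not used here. Assignment to the nearest gene end and the lists without dense bins were chosen after the data were seen. Of the main results under the alternatives, 62 moved outside the interval and 104 stayed within it. Of the others, 79 moved (45 higher, 34 lower) and 154 stayed. These counts cover shares and matched differences, and none of the matched differences changed sign. The dHx minus WT peak numbers of the gene lists are not in the counts, and some of them did change sign. The order of some pairs of shares also turned. WT-only over dHx-only at High RFP (43.0% and 30.6%) became 35.487% and 35.864% at equal length, and dHx High-only under Negative-only (38.9% and 54.4%) became 45.366% and 45.132%. The cause was not tested unless it is given below.

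When sharing needed 50% of the shorter peak, shares rose by construction. WT High peaks lacked a WT Negative peak in 51.194% and a dHx High peak in 44.967%. WT Middle lacked dHx Middle in 45.834%, WT Negative lacked WT High in 43.706% and dHx Negative in 31.585%. The dHx High peaks lacked WT High in 32.850% and dHx Negative in 41.068%, dHx Middle lacked WT Middle in 33.033%, and dHx Negative lacked WT Negative in 46.694% and dHx High in 56.207%.

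When peaks within 500 bp counted as shared, shares were lower by construction. In the same order they were 46.709%, 40.964%, 41.187%, 38.025%, 26.063%, 28.414%, 36.783%, 28.652%, 41.520% and 51.989%. The matched difference of WT High peaks without minus with a WT Negative peak was 18.725 points.

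With the strongest 20000 peaks of each list, the shares in that order were 42.605%, 33.130%, 33.325%, 42.345%, 31.580%, 33.285%, 41.480%, 33.490%, 32.050% and 41.370%. The matched difference was 14.593 points. Against the whole other list, the strongest 20000 lacked a peak of the other genotype in 18.405% (WT High), 18.420% (WT Middle), 11.905% (WT Negative), 12.645% (dHx High), 11.955% (dHx Middle) and 15.870% (dHx Negative).

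With lists of equal length (37129 peaks), the shares in that order were 44.151%, 35.487%, 35.301%, 43.750%, 34.081%, 35.864%, 45.366%, 35.598%, 34.862% and 45.132%. The matched difference was 16.353 points. Equal length makes both directions of a comparison nearly the same by construction.

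On autosomes only, WT Middle lacked dHx Middle in 40.935%, dHx Negative lacked WT Negative in 43.603% and dHx High in 53.758%. Without dense bins, WT High lacked dHx High in 41.728%, WT Middle lacked dHx Middle in 40.868%, and WT Negative lacked WT High in 39.970%. The dHx High peaks lacked dHx Negative in 39.472%, and dHx Negative lacked WT Negative in 42.233% and dHx High in 51.067%.

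With a window of 2.5 kb, more peaks stood near a gene end by construction. These were 45.471% of shared and 15.508% of WT-only WT High peaks, and 44.923% of shared and 24.181% of dHx-only dHx High peaks.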

Other observations

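The copy number and endoderm tests used here were chosen only after the result was seen, and the gene-end and dense-bin depth tests before it. Peaks present at both RFP-positive levels of a genotype were also looked up in the other genotype. Of 26761 such WT peaks, 3316 (12.4%) were missing from dHx at both levels, and of 22845 such dHx peaks 1276 (5.59%) were missing from WT. At equal length the shares were 8.77% and 8.11%. Near definitive endoderm genes 2 of 80 WT peaks (2.5%) were missing and near primitive streak genes 1 of 47 (2.13%, percentile 1.49). Near node genes it was 3 of 57 (5.26%), near lateral mesoderm genes 2 of 37 (5.41%) and near visceral endoderm genes 2 of 33 (6.06%). The highest share was 6 of 40 (15%, percentile 74.9), near blood and endothelium genes.

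By score in the High list, the strongest WT peak missing from dHx at both levels (mm10) lay 46.3 kb from Gja5, which encodes connexin 40 (chromosome 3, 96985871 to 96986378, score 92.6). Others lay inside Lepr, the leptin receptor (chromosome 4, 101769366 to 101770439, score 87.0), and inside Ulk4 (chromosome 9, 121268579 to 121271117, score 77.9). At equal length the Gja5 and Lepr peaks dropped out, so their WT Middle peaks were among the weaker ones, while the Ulk4 peak stayed. The strongest dHx peaks missing from WT lay 158 kb from Irs1 (chromosome 1, 82074570 to 82075219, score 92.9) and inside Calm2 (chromosome 17, 87437676 to 87438378, score 62.8). Alkbh5 had 16 of 26 WT peaks missing, Zswim2 13 of 14 and Llgl1 10 of 17, all outside dense bins. At Negative RFP the direction turned for Alkbh5 (0 of 18 WT-only against 16 of 33 dHx-only) and Llgl1 (0 of 12 against 16 of 28). In these 2 genes the list with the higher fitted background had more peaks at each level. Zswim2 kept its direction, with 13 of 28 against 0 of 21.

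The dense domains could reflect copy number that differs between the parents of the genotypes, depth with a threshold that admits weak regions, or accessibility at gene ends. The share of peaks within 1 kb of a gene end in WT Middle was −18.4 points (SE 0.398) in dense bins relative to elsewhere. Only 6.18% of the WT Middle peaks in dense bins stood there, so such gene ends account for few of them. These shares cover protein-coding genes only and were not matched on score, so accessibility was not excluded as such. The same genotype was higher at all 3 RFP levels in 35.7% of 14 domains (12.8 to 64.9), against 25% if the levels were independent. Among the strongest 20000 peaks, the highest share in dense bins was 2.03 times the lowest (SE 0.114), against 3.68 for whole lists. Copy number was set to need 1 sign in at least 3 in 4 domains, and fewer than 1 in 2 would speak against it. The interval lay below 3 in 4 but held both 1 in 2 and 25%. A ratio above 2 was set to speak against depth, and 2.03 passed this by less than its SE. Both values thus fell on the side against, neither clearly. Over the 14 domains, copy number and depth cannot be told apart. Of the 14 domains, 8 followed the order of the fitted backgrounds at each RFP level, the 5 on chromosome X among them. Those 5 were covered mainly in WT Middle. At 4 to 5 Mb it had 160 kb, against 46.7 kb in dHx Negative, which had the higher background. The chromosome 2 domain (175 to 178 Mb) did not follow the order, with 270 kb in WT Middle and 720 kb in dHx Middle. Nor did the chromosome 4 domain at 146 to 148 Mb, with 269 kb in WT Negative and 63.3 kb in dHx Negative. In both cases the list with the lower fitted background was covered more.

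Peaks missing from dHx at both RFP-positive levels were not concentrated near definitive endoderm genes, with a percentile of 0.23 in the opposite direction. Loss there cannot be excluded by this percentile, because weak peaks were missing more often and a list with strong peaks would stand low. A hypothesis is that FoxA2 without the helix may still hold open the regions near endoderm genes, although the streak list was as low and the random sets were not matched on peak strength. Reads of each sample, drawn to equal depth and counted at the WT High peaks near Cxcr4, Krt18 and Cdh1, would test it. It would be wrong if those regions had lower counts in dHx in every sample.

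Copy number could be tested with genomic DNA of the embryos of both genotypes, by coverage of the zinc finger genes of chromosome 2 (175 to 178 Mb) and chromosome 4 (146 to 148 Mb). The share of domains with 1 sign, 35.7%, does not decide it for these 2 domains, since it was taken over all 14. Of the 14, 8 followed the order of the fitted backgrounds at each RFP level. Among those 8 were the 5 on chromosome X, which were covered mainly in WT Middle.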
